A study of Mus musculus with 32 samples.

How the data were processed

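RNA of 32 samples from 4T1-Luc tumours was measured on single-colour Agilent mouse arrays: 12 PECAM-1 selected (EC) and 12 bulk samples at 1300 mm3, and 8 bulk samples of tumours resected at day 9 or at 600 mm3. The labels number the mice within each treatment, so that replicates are separate animals and both fractions of a tumour at 1300 mm3 share a number. Per the file headers, the scanner files hold intensity values made by Agilent Feature Extraction 10.7.3.1, background subtracted and detrended within each array and not scaled between arrays, while the submitters' notes name version 9.1. The deposited table of all samples also holds intensity values on a linear scale that the authors normalised in R by a method not stated. The medians of its columns lie close together, between 120 and 126, and its centring method stays unknown. The protocol text is the same for all samples and states digestion for each of them.

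Of 59305 spots that are not controls, 55681 different probes were kept, with replicate spots averaged. The files name no gene symbols, so probes were named by matching their RefSeq accession to a table of mouse genes of build GRCm38.p6: 26582 probes were named, for 20145 genes, of which 5370 have more than 1 probe. Of the unnamed probes 16194 carry genomic intervals, 11371 other accessions and 1534 RefSeq accessions absent from the table; all 29099 were tested apart. Each gene is represented by its brightest probe, chosen over all arrays without regard to group. Another tested probe of a called gene was called the other way for 133 genes of the resistant EC comparison with vehicle, 120 of resistant against sensitive, 173 of EC against bulk, 23 of the pooled EC, 3 and 12 of the bulk resistant comparisons, and none elsewhere. Kdr has 2 tested probes that differ, and both are given.

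Values are log2 of the processed signal minus the 75th percentile of the array. A gene was tested in a set of arrays when its probe was well above background, by the scanner software's own call, on at least as many arrays as the smallest group has, 4, or 2 for the smaller tumours. Where no array of a group had the gene well above background, the difference is given as a bound, computed against the lowest signal called well above background on each array, also where that group is only 1 of those averaged or set in a difference. No signal was at or under 0 and no probe was saturated. The precision is limited by the number of arrays; residual degrees of freedom were 9, 9, 4 and 9 in the fits of EC, bulk at 1300 mm3, smaller tumours, and both fractions together.

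Genes were tested with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8), with lmFit, contrasts and eBayes, Benjamini-Hochberg adjustment over all genes of a comparison, and a threshold of 0.05. Adjusted p values without another name are from limma. The 15 comparisons are sunitinib, sensitive and resistant against vehicle and resistant against sensitive in each fraction at 1300 mm3, sunitinib against vehicle at day 9, at 600 mm3, averaged over both and as their difference, EC against bulk within mice, and the sensitive and the resistant effect in EC against bulk. Standard errors (SE) are limma's moderated ones; SD is between arrays. In 461 tests, 31 gene lists were set against all other genes with camera at a preset correlation of 0.01, which called 145; 0 of them hold with a correlation estimated from the data, and fry, which asks only whether a list moves on balance, called 56. In 53 list tests the median, mean and test differ in sign, and camera called 0 of these. The mean of each list per array (list score) was compared by exact permutation of arrays, two-sided, and adjusted over the lists. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

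The lists hold markers of endothelial, lymphatic endothelial, mural (pericyte and smooth muscle), fibroblast, tumour epithelial, macrophage, neutrophil, T and NK, B and plasma, platelet, erythroid, adipocyte and skeletal muscle cells, and genes of VEGF response and tip cells, Notch, receptors inhibited by sunitinib, their ligands, other pro-angiogenic factors, hypoxia, glycolysis, proliferation (cell cycle), basement membrane, type I interferon response, antigen presentation, inflammatory cytokines, immediate early and dissociation stress, mesenchymal transition, TGF-beta response, ER and amino acid stress, cholesterol synthesis and lysosome. Groups, comparisons, lists, the main setting, most alternatives and the rule for named genes were set before the data were examined. The rule takes, per comparison, the 8 largest rises and falls among called genes whose arrays do not overlap, the 3 leading members of each called list, and always Kdr, Flt1, Pdgfra, Pdgfrb, Kit, Csf1r, Vegfa and Pecam1; where fewer than 5 genes passed, the 5 smallest p of each direction are given as values. Of the genes that the rule names, 1 is not reported here. Fixed later were the naming of genes by accession, the rule for bounds, the exact tests of list scores, the way overlap is counted in differences of effects, and naming, as well, the largest changes among genes measured on every array. Counts under 4 scalings had been seen by then, with the main setting unchanged.

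Alternatives were quantile scaling, normexp background correction with an offset of 50 (on median signals, since mean signals are not in the files), the deposited values, no filter on dim probes, the mean of a gene's probes, mouse numbers as a block, slide as a block, the tumour epithelial score as a covariate, a joint fit of 24 arrays with mouse as a random block (consensus correlation 0.201 in EC and 0.202 in bulk), and leaving out each array. With normexp the median of all genes went from 0.01 to 0.12 in pooled EC, from 0.03 and 0.04 to 0.24 in resistant EC against vehicle and against sensitive mice, and from -0.04 to 0.16 in the resistant difference of fractions (0.09 with quantile scaling, 0.06 with the deposited values); no other median moved by more than 0.1 under a scaling. Directions with normexp are read relative to that. Chosen after seeing the data were normexp with the medians against vehicle in EC brought to those of the main scaling, blocks with resistant mouse 4 as mouse 6, genes well above background on every array, leaving out 2 doubted bulk arrays or their mice, 1 slide alone, EC against bulk in resistant mice alone, and the muscle score as a covariate. Mouse numbers were checked for pairing across treatments by correlating residuals. Sensitive and resistant EC arrays were taken as possibly paired, with r of 0.138 to 0.268 across genes in 3 pairs, 2 of them best with their own number. Day 9 sunitinib and vehicle arrays had r of 0.152 in both pairs, values that 2 arrays per group force to be equal. The data files of resistant mouse 4 carry the number 6; its title was followed, and blocks and splits were also made with 6, which leaves 2 pairs. In simulated data with added changes of 1 and 2 on the log2 scale, the fits recovered 57% and 89% in sensitive EC against vehicle, 43% and 94% in resistant EC against vehicle, 30% and 80% in sensitive bulk, 5% and 73% at day 9, 1% and 61% at 600 mm3, 0% and 0% in the difference of both stages, and 5% and 56% in the sensitive difference of fractions. A raised list was called in 15 of 15 comparisons by camera and in 14 with an estimated correlation. The simulated genes varied independently, so this does not show how either test performs where genes of a list vary together.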

Results

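Tumours of 4T1-Luc, a luciferase-marked mouse mammary carcinoma line, grew in the mammary fat pad of female Balb/C mice that received vehicle or 40 mg/kg sunitinib, an inhibitor of receptor tyrosine kinases that include the VEGF and PDGF receptors. The 32 single-colour arrays hold RNA of a fraction selected with beads against PECAM-1, an endothelial surface protein, called the EC fraction here, and RNA of the digested tissue left after that selection, called bulk. At a tumour size of 1300 mm3 each fraction has 4 arrays from mice labelled sensitive to sunitinib up to day 8, 4 from mice labelled resistant, and 4 from vehicle mice, and the mouse numbers in the labels join both fractions of a tumour. Bulk tumours resected at day 9 and at 600 mm3 have 2 sunitinib and 2 vehicle arrays each. The share of probes well above background was 79.9% to 86.4% on the EC arrays of sensitive mice and 80.4% to 82.2% on those of vehicle mice, but 46.1% to 53.0% on those of resistant mice. It was 69.9% to 82.4%, 55.3% to 83.5% and 65.7% to 70.3% on the bulk arrays of sensitive, resistant and vehicle mice, and 67.2% to 79.7% on the 8 arrays of smaller tumours. All 8 resistant arrays lie on a slide of their own, so slide and resistance cannot be told apart in any comparison with resistant mice. On the other slides all sunitinib arrays lie in column 1 and all vehicle arrays in column 2. Column and treatment cannot be told apart there. The number of arrays limits the precision of every value below.

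**Figure D1:**
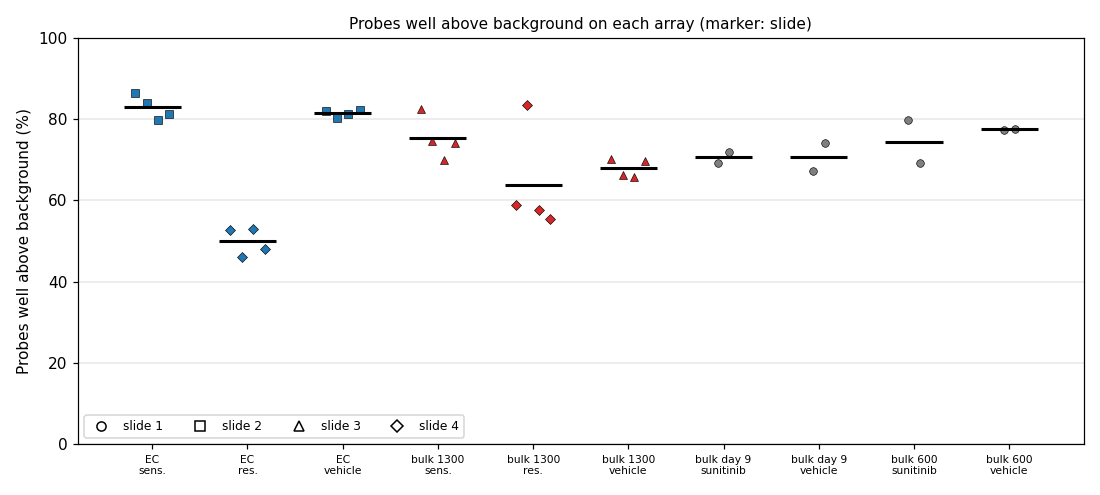
Percent of probes well above background on each of the 32 arrays, by group, with the slide shown by the marker and the group mean by a line. The 4 EC arrays of resistant mice lie between 46.1% and 53.0%, below all other arrays, and bulk resistant mouse 2 lies at 83.5% while the other bulk resistant arrays lie between 55.3% and 58.8%.

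What the bead selection separated was asked first, by comparing the EC fraction with the bulk of the same 12 tumours. Endothelial genes were far higher in the EC fraction: 27 of 28 measured members rose, with a median log2 difference of 4.57. The transcription factor Sox17 was at least 91.4-fold higher by its brighter probe, while its other probe rose by 4.19 (SE 0.25). The guidance receptor Robo4 rose by 6.24 (SE 0.46, n = 12 mice), Mmrn2 by 6.15 (SE 0.45), the junction cadherin Cdh5 by 6.03 (SE 0.41), and Pecam1, the selected protein's own gene, by 2.89 (SE 0.24). Glycam1, a ligand of high endothelial venules, was at least 44.3-fold and Ldb2 at least 59.5-fold higher. Of the 9 measured receptors that sunitinib inhibits 6 rose and 2 fell: Flt1 rose by 2.29, Csf1r by 2.22, Kit by 2.01 and Pdgfrb by 0.93, while Pdgfra fell by 0.95. Kdr, the main VEGF receptor, has 2 measured probes: the brighter, used throughout, had a difference of 0.35 (SE 0.14, adjusted p = 0.0535), while the other rose by 4.66 (SE 0.26). Of 20 VEGF-responsive and tip cell genes 16 rose and 2 fell, with Esm1 at 4.69 and the vessel-destabilising ligand Angpt2 at 3.78, and 9 of 14 Notch genes rose, with Notch4 at 3.40 and the ligand Dll4 at 2.74. Vegfa rose by 1.01 (SE 0.22).

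Other cell types moved with the selection as well. All 16 macrophage genes rose in the EC fraction, with a median of 2.19 (the mannose receptor Mrc1 2.94, Adgre1 2.90). Mural cell genes rose in 12 of 13 cases (Rgs5 2.60), lymphatic genes in 5 of 6 (the hyaluronan receptor Lyve1 3.77; Mmrn1 at least 9.85-fold), and platelet genes in 6 of 9 (Selp 2.92, platelet factor Pf4 2.19). Other pro-angiogenic factors rose in 10 and fell in 2 of 18 cases (Cxcl12 4.28, other probe 0.70; endothelin Edn1 3.90), and inflammatory cytokine genes rose in 17 and fell in 3 of 22 (Sele 3.32, Il6 2.73). All 16 tumour epithelial genes fell (keratin Krt7 -1.90, claudin Cldn4 -1.90). Of 18 T and NK cell genes 15 fell (Cd8a -2.54, Ifng -2.50), and 3 of 5 red cell genes fell (Alas2, the erythroid heme synthesis enzyme, -3.02; globin Hba-a1 -2.90). The checkpoint receptor Pdcd1 fell by 2.90, and 22 of 33 cell cycle genes fell while 3 rose (mitotic kinesin Kif11 -1.06). Basement membrane genes rose in 8 and fell in 1 of 12 cases, interferon response genes rose in 15 and fell in 2 of 20, lysosome genes rose in 11 and fell in 1 of 19, and immediate early genes, which tissue digestion induces, rose in 8 of 22.

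Of 18285 genes tested with limma, 9468 passed an adjusted p of 0.05, 4117 higher and 5351 lower in the EC fraction, and 18.3% of genes had the same sign in all 12 mice, where chance gives 0.0488%. Camera called 18 lists, and none held with a correlation estimated from the data (adjusted p = 0.193 for endothelial, 0.289 for macrophage, 0.353 for tumour epithelial genes, and 0.114 for the tip cell, Notch, receptor, platelet and other pro-angiogenic lists). The exact permutation p of the endothelial score was 0.000488, two-sided, the smallest that 12 pairs can give. Adjusted over the list alone, 28 of 28 endothelial, 16 of 16 macrophage and 16 of 16 tumour epithelial genes passed. The 13 lists that camera did not call had medians of -0.43 (fibroblast), -0.49 (neutrophil), 0.42 (B and plasma cell), 0.17 (adipocyte), -0.98 (skeletal muscle), -0.69 (ligands of the target receptors), 0.03 (hypoxia), -0.27 (glycolysis), 0.15 (antigen presentation), 0.08 (mesenchymal transition), 0.07 (TGF-beta response), 0.01 (ER and amino acid stress) and -0.19 (cholesterol synthesis). Both fractions share a slide only in resistant mice, where 94 genes passed (382 without resistant mouse 2) and the endothelial median was 3.63, both computed after the data had been seen.

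**Figure D2:**
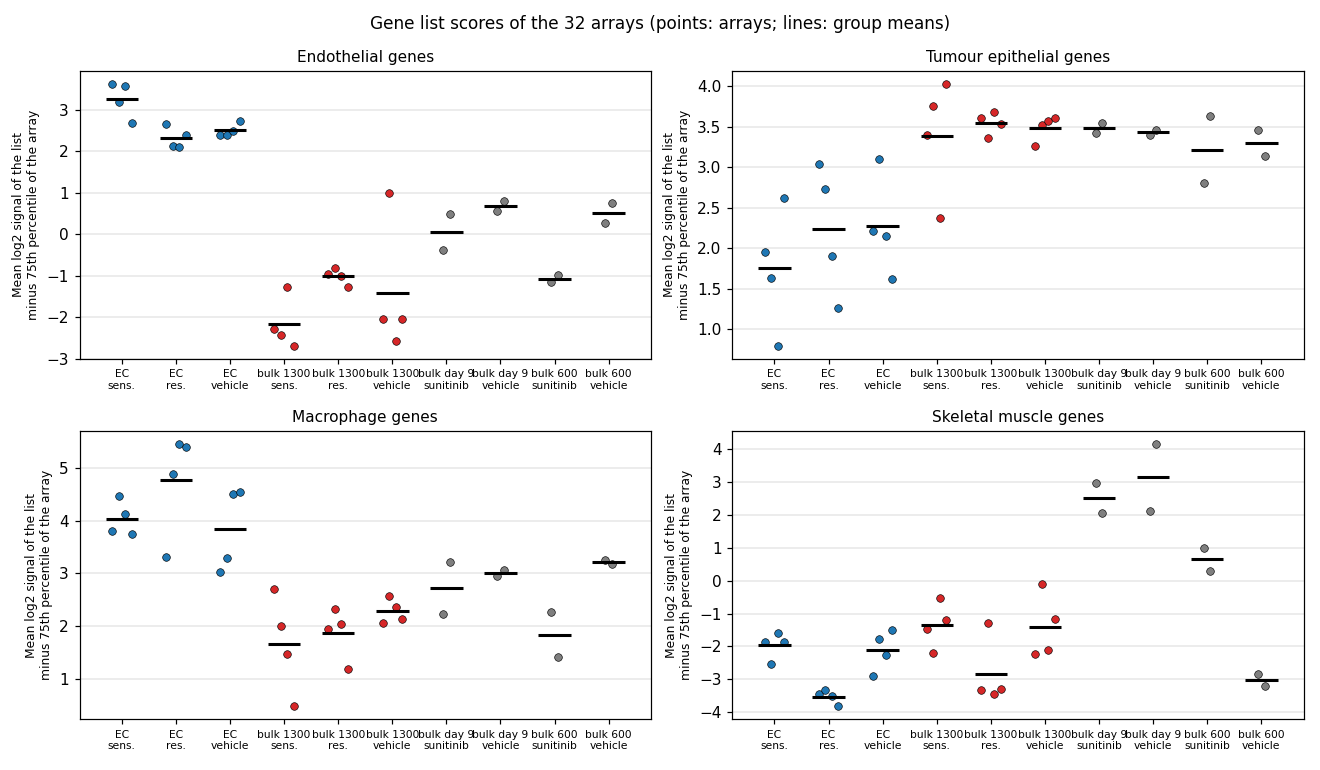
Mean log2 signal of the endothelial, tumour epithelial, macrophage and skeletal muscle lists, minus the 75th percentile of each array, for the 32 arrays by group, with lines at group means. Endothelial scores are highest on EC arrays (group means 2.33 to 3.27), bulk vehicle mouse 3 at 0.99 lies apart from the other vehicle bulk arrays at 1300 mm3, and muscle scores are highest in day 9 tumours (group means 2.51 and 3.15).

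The EC fraction of sensitive mice was compared with that of vehicle mice. The label sensitive covers the time up to day 8, and no day of resection is given at 1300 mm3, so time under treatment is unknown. No single gene passed the test. The endothelial genes lay together on the higher side, a list call that did not hold with an estimated correlation (adjusted p = 0.295). All 28 had a higher mean in sensitive mice, with a median log2 difference of 0.77. Ecscr, an endothelial adhesion and signalling protein, had the smallest p, with a difference of 1.27 (SE 0.20, n = 4 against 4, adjusted p = 0.588). Further values were 1.30 for the vascular homeobox gene Meox1, 1.18 for Bace2, 1.13 for the junction protein Esam, 1.23 for Btbd3 and 1.08 for the phosphatase Ptprb. VEGF-responsive and tip cell genes had a median of 0.51 (19 of 20 higher; Angpt2 1.19, Apln 1.07), Notch genes 0.42 (12 of 14 higher), and the receptors sunitinib inhibits 0.38 (7 of 9 higher). Among those receptors Ret stood at 2.15 (SE 0.63), Flt1 at 1.03 (SE 0.32, adjusted p = 0.737), Kit at 0.66, Pdgfrb at 0.39, Csf1r at 0.18 (other probes -0.22 and -0.08), Kdr at 0.15 (other probe 1.06, adjusted p = 0.72) and Pdgfra at -0.12, and Vegfa stood at -0.33 and Pecam1 at 0.71. Mural cell (median 0.39), basement membrane (0.48; Nid2 0.79), lymphatic (0.51) and cell cycle genes (0.10) were also called higher by camera. None of these held with an estimated correlation (adjusted p = 0.583 or above). On the lower side camera called tumour epithelial (-0.46; Cldn4 -1.27), neutrophil (-0.62; Ngp -1.54), inflammatory cytokine (-0.30; the granulocyte growth factor Csf3 -1.34) and immediate early genes (-0.17). None of these held either (adjusted p = 0.612). Single genes with small p on that side were Trerf1 at -0.68 and Khdc4 at -0.52.

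Limma called 0 of 17945 genes between these groups, with 971 at an unadjusted p under 0.05, and 4.49% of genes did not overlap between groups, where chance gives 2.86%. None of the 12 list calls held with an estimated correlation (adjusted p = 0.295 for the endothelial and receptor lists, 0.343 for tip cell and Notch, 0.583 for basement membrane, 0.964 for cell cycle and 0.612 for the others). Adjusted over the list alone, 22 of 28 endothelial, 2 tip cell and 2 receptor genes passed. The exact permutation p of the list score was 0.0571 for endothelial genes and 0.0286 for tip cell, Notch and receptor genes, two-sided, the last being the smallest that 4 against 4 can give, and 0.295 after adjustment. Both groups share a slide, on which they lie in different columns, and the count was also 0 from that slide alone. Slide as a block tests nothing here, since only resistant arrays lie on the other slide and the fit stays the same. The mean tumour epithelial score was 1.76 on these sensitive arrays and 2.28 on the vehicle arrays, and with that score as a covariate the epithelial median was 0.01. The cell cycle median was -0.06 without vehicle mouse 2 and the neutrophil median 0.13 without vehicle mouse 5. With 1 array left out, 10 of the 12 called medians and 9 of the 23 named values changed sign or moved by more than 1.5 times, and 7 lists lost their call in some fit. At their smallest the medians were 0.64 for endothelial, 0.32 for tip cell, 0.33 for Notch, 0.23 for receptor, 0.18 for mural cell, 0.29 for basement membrane and 0.18 for lymphatic genes (which lost the call in 8 of 12 fits), and -0.02 for cytokine and -0.17 for epithelial genes, with Ngp at -0.38 and Cldn4 at -0.67.

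The EC fraction of resistant mice was then compared with that of vehicle mice. Antigen presentation genes were higher in resistant mice: 13 of 19 rose, with a median log2 difference of 0.82, among them the chemokine Cxcl9 by 1.44 (SE 0.36, n = 4 against 4), the guanylate-binding protein Gbp3 by 1.17 (SE 0.17) and the MHC class II gene H2-Eb1 by 1.12 (SE 0.31). No list call of this comparison held with an estimated correlation (adjusted p = 0.889 or above). Cell cycle genes rose in 15 and fell in 1 of 33 cases, with the mitotic kinases Aurka and Plk1 at 1.30 and 1.28 and Cdc20 at 1.20. Interferon response genes rose in 8 of 20 cases (Cxcl10 1.25, Isg15 0.89, its other probe 0.13, adjusted p = 0.767) and macrophage genes in 3 of 16 (the fractalkine receptor Cx3cr1 1.86, complement gene C1qc 1.47), beside a mean macrophage score of 4.76 on these arrays and 3.84 on the vehicle arrays. Of all 17945 genes tested, 3439 were called higher, a share near that of the macrophage genes. Cholesterol synthesis genes rose in 9 of 19 cases (Insig1 1.57, Msmo1 0.98), glycolysis genes in 8 of 17 (lactate dehydrogenase Ldha 0.71, other probes 0.48 and 0.95, the first not passing), lysosome genes in 6 of 19, hypoxia genes in 7 of 23 with 1 fall (carbonic anhydrase Car9 1.02), and ER stress genes in 7 of 18 with 1 fall (the chaperones Dnajb9 1.21 and Hsp90b1 1.03). Adipocyte genes fell in 6 of 10 cases, with the adipokine Lep at least 7.87-fold lower and Plin4 at -2.26. Lep was well above background on no resistant EC array. Adipocyte scores were also low in resistant bulk on the same slide, at -4.49 to -4.26 apart from mouse 2 at -1.22. Vehicle bulk stood at -3.375 to -2.118, so a fall shared by the slide cannot be told apart here.

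Endothelial genes did not move as a group between resistant and vehicle mice: 2 of 28 fell, none rose, and the median was -0.13 (camera adjusted p = 0.929). Kdr fell by 0.68 by its brighter probe (SE 0.21, adjusted p = 0.0197), while its other probe stood at 0.50 (adjusted p = 0.152) and the mean of both at -0.09, which did not pass. Flt1 stood at -0.67 (SE 0.32, adjusted p = 0.101), Pecam1 at -0.51, Pdgfrb at -0.52, Kit at -0.02, Pdgfra at 0.15, Csf1r at 0.89 and Vegfa at -0.32 (other probe 0.33), none of which passed. With 1 array left out Vegfa ranged from -0.598 to 0.001. Among the largest single rises were S100g, a calcium-binding protein, at least 3.88-fold higher, the transcription factor Tbx22 by 3.67 (SE 0.95), the muscle gene Cmya5 by 3.21 (its other probe stood at -0.36, adjusted p = 0.532) and Wfdc18 by 3.01. Prg2, the major basic protein of eosinophil granules, fell by 6.36 (SE 0.93) and Gpr37l1 by 5.53, and the transcription factor Sox14 was at least 13-fold and the growth factor Bmp10 at least 9.20-fold lower. Of genes measured on every array, the serpin Serpinb2 fell by 5.08 (SE 0.86), Mdh1b by 4.32 and the eosinophil ribonuclease Ear2 by 4.11.

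Limma called 8300 of 17945 genes, 3439 higher and 4861 lower, and 40.0% of genes did not overlap between groups, where chance gives 2.86%. Beside 46.1% to 53.0% of probes well above background on the resistant arrays, 41.4% of calls were higher in the main scaling, but 72.8% with normexp, 49.9% with quantile scaling and 51.7% with the deposited values. The median of all genes was 0.03 in the main scaling and 0.24 with normexp. With that median brought back to 0.03, normexp gave 4648 genes, 40.3% of them higher. Of genes well above background on every array, a filter that by construction removes genes that fell out of detection, 3341 rose and 1128 fell. None of the 10 list calls held with an estimated correlation (adjusted p = 0.962 for macrophage and 0.889 for the others), and adjusted over the list alone 15 of 19 antigen presentation and 16 cell cycle genes rose. Leaving out 1 array at a time, 26 of the 30 named genes that passed kept their call, and C1qc, Isg15, Car9 and Kdr did not, while 4 of the 10 called medians moved by more than 1.5 times. Of all 37 named values 6 changed sign or moved by more than 1.5 times, and 2 lists lost their call in some fit. Slide and group coincide, so that a batch effect of any size is contained in these counts.

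Resistant and sensitive mice, both given sunitinib, were also compared in the EC fraction. Endothelial genes were lower in resistant mice, with 23 of 28 falling and a median log2 difference of -0.93: Flt1 fell by 1.70 (SE 0.32, n = 4 against 4), Ptprb by 1.60, the angiopoietin receptor Tek by 1.5, Pecam1 by 1.22 and Kdr by 0.83 (SE 0.21; its other probe stood at -0.56, adjusted p = 0.11). Here too no list call held with an estimated correlation (adjusted p = 0.687 or above). Mural cell genes fell in 11 of 13 cases (desmin Des -2.05, smooth muscle myosin Myh11 -1.93, the pericyte receptor Notch3 -1.71), with Pdgfrb at -0.91 and Kit at -0.68. Adipocyte genes fell in 6 of 10 cases, Lep at least 7.31-fold. Adipocyte scores in resistant bulk, mouse 2 apart, were -4.49 to -4.26 beside -3.272 to -2.722 in sensitive bulk. A fall shared by the slide cannot be told apart here either. Antigen presentation genes rose in 14 of 19 cases (H2-Aa 1.43), interferon response genes in 8 of 20 (Isg15 1.12, other probe 0.44, adjusted p = 0.271; Stat2 1.00), glycolysis genes in 11 of 17, cell cycle genes in 14 of 33 with 1 fall (Cdc20 1.01), cholesterol synthesis genes in 8 of 19 (Insig1 1.47), lysosome genes in 8 of 19, ER stress genes in 7 of 18 (Dnajb9 1.32), hypoxia genes in 7 of 23 with 1 fall, and macrophage genes in 1 of 16 (Cx3cr1 1.49). Over all genes 3153 of 17945 were called higher, a larger share than in the macrophage list. Immediate early genes rose in 7 of 22 cases with 1 fall (the heat shock protein Dnajb1 1.39, Ier2 1.23), while the median of the list, 0.37 here, was -0.03 with quantile scaling and -0.02 with the deposited values. Other rises were the interferon gene Ifnb1 by 2.63, the hypoxia-linked coregulator Cited2 by 1.84 and the nuclear RNA Neat1 by 1.74. A probe of Fmr1nb rose by 3.54, while another probe of it, not well above background on any resistant array, was called lower. Bmp10 was at least 9.06-fold lower, and among genes measured on every array Mdh1b fell by 4.33 and Serpinb2 by 3.84. Csf1r at 0.71, Pdgfra at 0.27 and Vegfa at 0.01 did not pass.

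Limma called 8301 genes here, 3153 higher and 5148 lower, and 42.5% of genes did not overlap, where chance gives 2.86% if the arrays are not paired. The share of calls that were higher was 38.0%, but 67.4% with normexp (30.2% with the medians against vehicle brought back to the main ones), 45.9% with quantile scaling and 47.5% with the deposited values; of genes well above background on every array 3034 rose and 1335 fell. The 13 list calls did not hold with an estimated correlation (adjusted p = 0.862 for macrophage, 0.687 for the others), although 23 endothelial, 11 mural and 14 antigen presentation genes passed adjusted over the list alone. The exact permutation p of the endothelial, mural and antigen presentation scores was 0.0286 over all 35 splits and 0.0738 after adjustment. This leaves out that sensitive and resistant arrays may pair by number, where no p under 1 in 8 is possible. With the mouse numbers taken as 3 pairs in a block, 8454 genes passed. The data files of resistant mouse 4 carry the number 6, and with the 2 pairs then left 7323 passed. Leaving out 1 array at a time took the calls of Pdgfrb, H2-Aa and Kit away, and 24 of the 27 named genes that passed kept theirs, while 1 of the 13 called medians moved by more than 1.5 times. The macrophage list lost its call in 5 of 12 fits and the hypoxia list in 4. Tumour epithelial scores averaged 2.24 in resistant and 1.76 in sensitive mice.

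When both sunitinib groups were set together against vehicle in the EC fraction, the question the series design states, the mucin-like gene Fcgbp rose by 2.55 (SE 0.69, n = 8 against 4), Chp2 by 1.51, Ildr1 by 1.34, Hoxd10 by 1.15, the mitotic gene Gtse1 by 0.96 and the granzyme inhibitor Serpinb9 by 0.84. S100g was at least 2.40-fold and the MYC family gene Mycl at least 2.41-fold higher. The nuclear receptor Rorb was at least 2.85-fold lower, Smco1 fell by 1.60 and Prr7 by 1.26. Cell cycle genes rose in 10 of 33 cases with 1 fall (Aurka 0.86, Plk1 0.79), cholesterol synthesis genes in 5 of 19 (Insig1 0.84), ER stress genes in 4 of 18 with 1 fall, and antigen presentation genes in 4 of 19 (Cxcl9 1.04, Gbp3 0.74). Endothelial (2 of 28; Erg 0.77, other probe 0.23, adjusted p = 0.683; Ecscr 0.76), tip cell (2 of 20), hypoxia (2 of 23), glycolysis (1 of 17), interferon response (1 of 20; Cxcl10 0.81) and macrophage genes (1 of 16) had few rises, and none of 19 lysosome genes passed. Of all 17945 genes tested, 1099 were called higher and 3317 lower. B cell genes fell in 3 of 9 cases (complement receptor Cr2 -1.82, Blk at least 1.84-fold) and adipocyte genes in 3 of 10 (Lep at least 2.91-fold, Cidec at least 2.22-fold). Kdr at -0.27, Flt1 at 0.18 and Vegfa at -0.32 (other probe 0.10) did not pass, but the other probe of Kdr rose by 0.78 (adjusted p = 0.0312).

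Limma called 4416 genes in that pooled comparison, 1099 higher and 3317 lower, and 1.32% of genes did not overlap, where chance gives 0.404%. The share higher was 24.9%, but 56.2% with normexp (1825 genes; 16.6% of 1371 with the medians brought back), 43.1% with quantile scaling (2871) and 45.2% with the deposited values (2579). The count was 1332 among genes well above background on every array, where the adipocyte median was 0.16, and 1465 in a joint fit of 24 arrays. The 13 list calls were all lost with an estimated correlation (adjusted p = 0.886), and adjusted over the list alone 11 cell cycle, 5 cholesterol and 4 antigen presentation genes rose. Since sensitive arrays alone gave 0 genes and resistant arrays 8300, the pooled calls include whatever sets the resistant arrays apart, slide or resistance, which cannot be told apart. Leaving out 1 array at a time, Cxcl10, Cxcl9, Erg and Fcgbp lost their call, 9 of the 13 called medians moved by more than 1.5 times, and 9 lists lost their call in some fit.

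In the bulk fraction at 1300 mm3 few genes separated sunitinib from vehicle. The phospholipase Plb1 was at least 9.16-fold higher in the pooled sunitinib mice, the secreted protein Wfdc18 rose by 3.90 (SE 0.74, n = 8 against 4), the transcription factor Tfap2b was at least 3.21-fold and Dppa2 at least 2.72-fold higher, the small nuclear RNA Rnu1b6 rose by 2.02 and histone H2ac6 by 1.41. Tm4sf4 fell by 1.68, the sulfotransferase Chst15 by 1.27 (other probe -0.17, adjusted p = 0.977), Npb by 0.96 (other probes -0.58 and -0.38, neither passing) and the NK receptor Cd244a by 0.82. None of 15 macrophage genes passed, with a median of -0.49, and none of 19 antigen presentation genes, with a median of 0.28. Adjusted over the list alone, 0 and 1 of them passed. Both lists were called by camera, and neither held with an estimated correlation (adjusted p = 0.969). Limma called 138 of 16972 genes, 8 higher and 130 lower, and 0.689% of genes did not overlap, where chance gives 0.404%. The count moved with every array left out: to 55 to 87 without a sensitive array, to 61, 82 and 83 without resistant mouse 1, 3 and 4, to 2590 without resistant mouse 2, and to 26 to 44 without a vehicle array. It was 20 with mouse number as a block, 2725 without the 2 doubted arrays, bulk resistant mouse 2 and bulk vehicle mouse 3, and 284, 270 and 70 with quantile scaling, deposited values and normexp, and none of the 10 named genes kept its call under every array left out.

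Bulk of sensitive mice against vehicle gave no gene. Macrophage genes had a median log2 difference of -0.82 (0 of 15 higher; Mrc1 -1.14), endothelial genes -0.81 (4 of 28 higher; Cdh5 -2.01), T and NK cell genes 0.94 (16 of 18 higher; Ifng 1.72, granzyme Gzmb 1.19) and tip cell genes -0.27 (5 of 20 higher; Nid2 -1.51). The single genes with the smallest p were Rnu1b6 at 2.20 and Plb1, at least 14.5-fold higher, on the higher side, and the oxidase subunit Cybb at -1.47 and the peptide Grp at -2.98 on the lower side. Kdr stood at 0.40 (other probe -1.08), Pecam1 at -0.55 and Vegfa at -0.23 (other probe 0.04). Limma called 0 genes, with 1082 at an unadjusted p under 0.05, and 7.49% did not overlap, where chance gives 2.86%. It called 7 without resistant mouse 2, 2 with mouse number as a block and 8 from the shared slide alone. On that slide the groups lie in different columns. The 4 list calls had an adjusted p = 0.969 with an estimated correlation, no member passed adjusted over the list alone, and with 1 array left out all 4 medians and 8 of the 12 named values changed sign or moved by more than 1.5 times. The T and NK cell median ranged from 0.35 to 1.59 and lost its call in 5 of 12 fits, Ifng came to 0.77, Gzmb to 0.35, Cdh5 to -0.84, Nid2 to -0.61 and Mrc1 to -0.62 at their smallest. The endothelial median was 0.06 without vehicle mouse 3, whose endothelial score was 0.99 beside -2.58 to -2.05 in the other vehicle mice.

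Bulk of resistant mice against vehicle showed rises of the mucosal scavenger gene Dmbt1 by 5.04 (SE 1.20, n = 4 against 4), Wfdc18 by 3.59, the galectin Lgals7 by 2.22 (SE 0.36), the phosphatase Alpl by 2.12 and the interferon-induced Gbp4 by 1.74, and Plb1 was at least 5.77-fold higher. The cytochrome Cyp2e1 fell by 3.73 (other probe -1.03, adjusted p = 0.518) and Gml2 by 3.91, and the myogenic factor Pax7 was at least 7.18-fold lower. Kdr fell by 1.16 by its brighter probe (SE 0.25, adjusted p = 0.0161), while its other probe stood at -0.32 (adjusted p = 0.821). Antigen presentation genes rose in 3 of 19 cases (Gbp3 1.09, Igtp 0.99; 5 adjusted over the list alone), the single list call (adjusted p = 0.964 with an estimated correlation). Against sensitive mice, resistant bulk had Sox17 at least 7.75-fold higher (its other probe stood at -0.07) and rises of chromogranin Chga by 3.1, keratin Krt20 by 2.83, Lgals7 by 2.57, the kinase Dstyk by 1.98 and Eid3 by 1.95, and Kdr fell by 1.56 by its brighter probe (SE 0.25), its other probe standing at 0.76 (adjusted p = 0.495). There 3 of 19 antigen presentation genes rose (Gbp3 1.21; 3 adjusted over the list alone; adjusted p = 0.98 with an estimated correlation). Of the 12 named genes against vehicle and 8 against sensitive mice, 6 and 6 kept their call with any array left out. Limma called 1313 genes against vehicle, 336 higher and 977 lower, and 2050 against sensitive mice, 560 higher and 1490 lower, with 13.3% and 17.7% of genes not overlapping, where chance gives 2.86%. Without resistant mouse 2 the counts were 5500 and 6385. The first was 678, 664 and 715 without resistant mouse 1, 3 and 4, and 701 and 729 without vehicle mouse 2 and 5. The second was 1181, 1212 and 1146 without resistant mouse 1, 3 and 4, and 1186 and 1237 without sensitive mouse 4 and 5. With mouse number as a block they were 418 and 785, or 131 and 217 with resistant mouse 4 taken as mouse 6. The share of the second that was higher was 27.3%, but 37.4% with the deposited values.

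Smaller tumours were compared in bulk tissue, 2 sunitinib against 2 vehicle mice at each stage, all on 1 slide. Treated and vehicle arrays lie in different columns of it. At day 9 no gene passed. Interferon response genes had a median log2 difference of 0.64 in treated tumours (18 of 20 higher; the antiviral enzyme Oas2 1.25), while endothelial genes had -0.68 (2 of 28 higher), fibroblast genes -0.83, neutrophil genes -0.87 (Retnlg -3.61), red cell genes -1.04, B cell genes -0.58 (the immunoglobulin joining chain Jchain -3.10), muscle genes -0.64, basement membrane genes -0.55, mural cell genes -0.48 and tip cell genes -0.41. The macrophage protein Cd5l stood at -5.70 (SE 0.70, adjusted p = 0.23), Serpinb10 was at least 2.95-fold lower, Kdr stood at -0.65 (other probe -0.24) and Vegfa at -0.27. Limma called 0 of 17443 genes, with 1387 at an unadjusted p under 0.05, 1 gene with each of the other scalings and 2 genes without vehicle mouse 2. Of all genes, 34.8% did not overlap, where chance gives 33.3%. The 10 list calls had an adjusted p = 0.813 with an estimated correlation (0.832 for muscle), no member passed adjusted over the list alone, and an exact permutation test of 2 against 2 cannot go below 0.333. The fibroblast median was 0.02 without sunitinib mouse 1 and the muscle median 0.16 without vehicle mouse 2. With 1 array left out 9 of the 10 medians and 4 of the 7 named values changed sign or moved by more than 1.5 times, and each list lost its call in some fit. At their smallest the medians were -0.09 for endothelial, -0.01 for tip cell, -0.12 for mural cell, -0.21 for basement membrane, -0.36 for neutrophil, -0.35 for B cell, -0.73 for red cell and 0.19 for interferon response genes.

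At 600 mm3 muscle genes were among the largest rises in treated tumours, and endothelial, mural cell and macrophage genes were among those that fell. No list call held with an estimated correlation (adjusted p = 0.287 or above). The fast myosin Myh4 was at least 452-fold, the muscle ubiquitin ligase Trim63 at least 189-fold and titin, Ttn, at least 124-fold higher. That bound is of the brightest probe of Ttn. Of its 3 other probes 1 passed, at 6.89, and the others stood at 3.15 and 3.89. Pdlim3 rose by 7.06 (SE 0.67, n = 2 against 2), Myl1 by 6.78, Tcap by 6.32, Actn3 by 5.62 and Acta1 by 5.37. Of the 11 fixed muscle genes 3 rose, 9 adjusted over the list alone, with a median of 2.76. Endothelial genes fell in 5 of 28 cases, 19 adjusted over the list alone, with a median of -1.76 (Icam2 -3.35), mural cell genes fell in 3 and rose in 1 of 13 (Cnn1 -3.78; 8 falls and 1 rise adjusted over the list alone), and no fibroblast gene of 16 passed, with a median of -1.44. Macrophage genes fell in 4 of 16 cases (Cx3cr1 -3.08, Aif1 -2.95), T and NK cell genes in 2 of 18 (the NK receptor Klrk1 -3.57), interferon response genes in 4 of 20, 19 adjusted over the list alone (Oas2 -3.04, Ifi44 -2.23), and antigen presentation genes in 3 of 19. Of 8 measured target receptors Kit fell by 2.42 and Pdgfrb by 2.14. The mast cell protease Mcpt2 (-6.5), the retinoid-binding Crabp1 (-5.29), smooth muscle actin Actg2 (-4.88), Lrrc15 (-4.62), Cd72 (-4.60) and the dendritic cell integrin Itgax (-3.95) fell as well. Tip cell genes had a median of -0.45 with 1 fall, Notch genes -0.51, basement membrane genes -0.55 and glycolysis genes 0.43, none of the last 3 with a passing member, and tumour epithelial genes, which camera did not call, had -0.08. Kdr at 0.56 (other probe -1.64), Flt1 at -0.41, Pecam1 at -0.89 and Vegfa at 0.28 (other probe 1.32) did not pass. With 1 array left out the sign changed for Kdr (to -0.01), Flt1 (to 0.161) and Vegfa (to -0.045).

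Limma called 283 genes at 600 mm3, 89 higher and 194 lower, and 53.9% of genes did not overlap, where chance gives 33.3%. Leaving out 1 array moved the count to 4 and 28 (vehicle mouse 3 and 4), to 63 and 28 (sunitinib mouse 3 and 4), and to 489 for either day 9 sunitinib mouse. Of the 23 named genes that passed 1 kept its call throughout, and 3 of the 13 called medians moved by more than 1.5 times. With the muscle score as a covariate, chosen after seeing the data, no gene passed, with the muscle median at -0.14, the tip cell median at 0.36 and the basement membrane median at 0.30. The other medians kept their sign, at -1.47 for endothelial, -2.21 for mural cell, -0.92 for fibroblast, -1.30 for macrophage, -3.34 for T and NK cell, -2.54 for interferon response, -1.62 for antigen presentation, -1.08 for receptor, -0.66 for Notch and 0.90 for glycolysis genes. The 13 list calls had an adjusted p = 0.287 with an estimated correlation, 0.534 for fibroblast, tip cell and basement membrane and 0.662 for glycolysis genes. Adjusted over the list alone, 11 macrophage, 11 T and NK cell, 6 antigen presentation, 3 receptor and 2 fibroblast genes fell.

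Averaged over day 9 and 600 mm3 no gene passed, and endothelial genes had a median of -1.15, all 28 on the lower side and 20 of them passing adjusted over the list alone. Fibroblast genes had a median of -1.08, mural cell genes -1.23, macrophage genes -0.92, red cell genes -1.83, T and NK cell genes -0.71, target receptors -0.97, tip cell genes -0.34, basement membrane genes -0.55, interferon response genes -0.43, antigen presentation genes -0.37 and muscle genes 1.25. All were called by camera, with an adjusted p = 0.341 with an estimated correlation, 0.369 for interferon. Adjusted over the list alone 10 macrophage, 8 mural, 3 receptor and 2 fibroblast genes were lower as well. The muscle gene Myoz2 came closest among single genes, at least 5.22-fold higher (adjusted p = 0.0627). With 1 array left out 6 of the 12 medians moved by more than 1.5 times. Limma called 0 genes, with 1743 at an unadjusted p under 0.05, 3 with normexp, 1 with the deposited values, 202 without day 9 sunitinib mouse 2, and 1 without sunitinib mouse 3 or vehicle mouse 4 of the 600 mm3 stage.

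The test of the difference between both stages called 29 genes, 23 of which had a higher effect at 600 mm3: among them the muscle genes Trim63, at least 605-fold, Ttn, at least 186-fold (other probes 3.84, 4.91 and 8.07, none passing), and Myoz2, at least 114-fold. Cd72 at -5.37, the surfactant gene Sftpc at -4.81 and Btn2a2, at least 4.52-fold, were among the 6 lower. By camera interferon response (median -2.14), T and NK cell (-1.69), mural cell (-1.70), antigen presentation (-1.30), macrophage (-1.12), endothelial (-1.07) and Notch genes (-0.75) had a lower effect at 600 mm3, and muscle (3.18), neutrophil (0.85), glycolysis (0.57) and hypoxia genes (0.52) a higher one. These had an adjusted p = 0.7 to 0.889 with an estimated correlation, and 17 of 20 interferon genes passed adjusted over the list alone. The count was 0 with pairs as a block or the muscle covariate, 15 with no filter, 2 to 7 without day 9 sunitinib mouse 1 or 2 or any 600 mm3 array, and 94 without day 9 vehicle mouse 2, and with 1 array left out 8 of the 11 medians moved by more than 1.5 times.

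Whether sunitinib acted differently on the fractions was tested within mice. For sensitive mice no gene passed, with 871 of 18285 at an unadjusted p under 0.05 by limma. Endothelial genes had a median difference of 1.58 toward EC (27 of 28 higher; Cdh5 2.84), tip cell genes 0.85 (Esm1 2.08), target receptors 0.77, macrophage genes 0.95, lymphatic 0.91, mural cell 0.55, basement membrane 0.34, other pro-angiogenic factors 0.27, cell cycle 0.26 and Notch 0.25, and T and NK cell genes -0.76, inflammatory cytokines -0.74, immediate early -0.68, neutrophil -0.57, epithelial -0.41 and glycolysis genes -0.21. These 16 lists were called by camera and none held with an estimated correlation (adjusted p = 0.0949 for tip cell, 0.105 for target receptor and 0.23 for endothelial genes, up to 0.737). The exact permutation p was 0.0286 for tip cell and receptor scores, the smallest possible, and 0.354 after adjustment. The count was 2 without resistant mouse 2, and the immediate early median was 0.14 without vehicle mouse 3. With 1 mouse left out 12 of the 16 medians changed sign or moved by more than 1.5 times, and 8 lists lost their call in some fit. At their smallest the medians were 0.72 for endothelial, 0.64 for tip cell, 0.52 for receptor, 0.62 for macrophage and 0.47 for lymphatic genes, and -0.02 for cytokine, -0.25 for T and NK cell, -0.32 for neutrophil and -0.18 for epithelial genes, with Cdh5 at 1.63 and Esm1 at 1.33. Adjusted over the list alone 3 tip cell genes passed.

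For resistant mice 50 genes passed, 2 higher and 48 lower in the EC fraction relative to bulk. The kinase Cdkl1 had a difference of 2.15 (SE 0.28, n = 4 against 4 mice) and the POU factor Pou3f1 of 2.05. Prg2 fell by 5.90 and Foxp3, the regulator of regulatory T cells, by 3.99, and Serpinb10 was at least 8-fold, the lectin Clec4g at least 5.94-fold and the endothelial lipase Lipg at least 2.71-fold lower. Cell cycle genes had a median of 0.74, with none of 33 passing over all genes and 22 rises and 1 fall adjusted over the list alone, macrophage genes 1.48, cholesterol synthesis 0.54, lysosome 0.50, glycolysis 0.39, antigen presentation 0.38 and interferon 0.36, and neutrophil genes had -1.26 and T and NK cell genes -0.92. The 9 list calls had an adjusted p = 0.596 with an estimated correlation, 0.762 for T and NK cells. The glycolysis median was -0.02 with quantile scaling, and the antigen presentation median was -0.003 with quantile scaling and -0.02 with the deposited values. The share of higher calls was 4.0%, but 63.2% with normexp, 32.9% of 152 genes with quantile scaling and 19.7% of 183 with the deposited values. With 1 mouse left out 3 of the 9 medians moved by more than 1.5 times and no named gene kept its call in every fit. The count was 424 without resistant mouse 2 and 148 and 30 without resistant mouse 1 and 3, 27, 25 and 33 without sensitive mouse 2, 3 and 5, and 20, 28, 4 and 0 without vehicle mouse 2, 3, 4 and 5.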

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

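Of the tests of explanations in this part, only that of slide 4 in resistant bulk was fixed before its result was seen; the comparisons, and the scalings other than normexp with its median brought back, had been set beforehand. Of 252 groups of 4 values, 29 had an array far from the other 3, where chance gives 12.6.

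Calls in resistant EC against vehicle leaned to the lower side, 41.4% being higher, beside 49.9% with quantile scaling, 51.7% with the deposited values and 72.8% with normexp, which moved the median of all genes from 0.03 to 0.24; with that median brought back to 0.03 normexp gave 40.3%, but since this step largely fixes the balance itself, it stays open whether the correction of dim signals sets it. Of the genes called lower, 56.1% were well above background on no resistant EC array, against 18.9% of all tested genes and 0.174% of those called higher. In resistant bulk, which shares the slide, the 4305 of these lower genes that were tested had a median of -1.06, beside -2.02 in EC, and 87.9% were lower (47.8% of all genes), consistent with something shared by the slide. Since slide and resistance coincide, a biological difference of resistant tumours stays open and untested, for both fractions. A random division of the arrays is an unlikely account of the 8300 genes against vehicle, as 1 of 35 splits, the real one, gave as many (highest other 262). This is the smallest share that 35 splits allow, and it is not adjusted over the split tests. Every other split mixes arrays of both slides, so it cannot tell resistance from slide. Against sensitive mice the arrays may pair by number. If they do, only 8 splits part 3 pairs, too few to exclude chance (1 of 8 gave as many as 8301, highest other 0). If they do not, 1 of 35 splits gave as many (highest other 0).

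Bulk vehicle mouse 3 had an endothelial score of 0.99 beside -2.58 to -2.05 in the other vehicle mice, with a gap of 0.851 of the group's range. Its immediate early score of 1.57, below the 3.72 to 5.20 of the 23 other arrays at 1300 mm3, argues against RNA of the EC fraction mixed into it, and the endothelial score of 2.41 in the EC array of the same mouse, beside 2.39 to 2.73 in the others, argues against a swap of both. Over all genes it correlated better with the 8 arrays of smaller tumours (mean r 0.969) than with the 11 other bulk arrays (0.949), a difference of 0.02, which may point to tissue handled as the smaller tumours were, although the protocol text states digestion for all samples, so that handling without it rests on these scores and stays open. The other vehicle arrays went the opposite way (0.938 and 0.955, 0.957 and 0.959, 0.951 and 0.959). The design gives no biological explanation for a single mouse, and none was tested.

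At 600 mm3 camera called muscle genes higher and endothelial, mural cell, fibroblast, macrophage and T and NK cell genes lower in treated tumours, and no list held with an estimated correlation (smallest adjusted p = 0.287). The tumour epithelial median was -0.077, where the median SE of its genes was 0.38. This cannot tell whether muscle tissue diluted all other RNA, since scaling within each array takes out most of a shared drop. Such an equal drop alone would not set the endothelial median, -1.76, apart from the epithelial one. Of the 5 lists of other cell types, fat apart, that camera did not call, 3 had a median below 0 (lymphatic -0.93, platelet -0.59, red cell -2.62) and 2 had not (neutrophil 0.03, B cell 0.25), which leaves open whether the share of stromal and immune cells was lower against tumour cells. An effect of treatment stays open, since each arm has 2 mice. The muscle covariate, which itself differs between the arms (mean scores 0.65 and -3.03), left 0 genes but an endothelial median of -1.47 and a macrophage median of -1.30, so the lost calls say little.

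Bulk resistant mouse 2 lay apart from its group in several values, each given with its gap as a share of the group's range. Its share of probes well above background was 83.47% beside 55.32% to 58.77% (0.877), and its median signal was -1.27 beside -4.50 to -4.43 (0.976). Its scores were -2.17 for lymphatic genes beside -5.48 to -4.99 (0.85), -1.42 for platelet genes beside -3.04 to -2.79 (0.844), -1.22 for adipocyte genes beside -4.49 to -4.26 (0.929), -1.30 for skeletal muscle genes beside -3.46 to -3.30 (0.927) and 3.72 for immediate early genes beside 4.52 to 4.65 (0.859). Bulk vehicle mouse 3 also lay apart in other pro-angiogenic factors (-0.46 beside 0.42 to 0.55, 0.876), inflammatory cytokines (-0.32 beside 2.96 to 3.21, 0.927), immediate early genes (1.57 beside 4.58 to 4.75, 0.945) and Csf1r (5.77 beside 5.22 to 5.31, 0.838). In bulk resistant mouse 3 the receptor ligand score was 1.43 beside 1.26 to 1.28 (0.901), and in bulk resistant mouse 4 Csf1r was 3.95 beside 5.08 to 5.30 (0.837).

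Bulk sensitive mouse 5 lay apart in fibroblast genes (1.38 beside 2.33 to 2.51, 0.836), other pro-angiogenic factors (-0.26 beside 0.31 to 0.40, 0.864) and cell cycle genes (1.44 beside 1.82 to 1.89, 0.839), and bulk sensitive mouse 4 in glycolysis genes (5.80 beside 5.49 to 5.54, 0.831). EC resistant mouse 1 had platelet genes at -2.54 beside -1.82 to -1.72 (0.883), receptor ligands at 1.48 beside 0.99 to 1.03 (0.912), hypoxia genes at 2.79 beside 3.09 to 3.15 (0.85), glycolysis genes at 5.32 beside 5.80 to 5.85 (0.905) and Csf1r at 6.58 beside 8.13 to 8.43 (0.837). EC resistant mouse 3 had B cell genes at -4.96 beside -3.93 to -3.79 (0.884). EC sensitive mouse 5 had antigen presentation genes at 5.16 beside 4.64 to 4.69 (0.898), and EC sensitive mouse 2 ER stress genes at 2.46 beside 2.73 to 2.78 (0.836). EC vehicle mouse 5 had red cell genes at -0.15 beside -1.50 to -1.41 (0.933) and adipocyte genes at -0.23 beside -2.10 to -1.91 (0.897), and EC vehicle mouse 2 interferon response genes at 2.21 beside 2.91 to 2.95 (0.944).

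Differences between effects were called by limma and camera for 29 genes and 11 lists at 600 mm3 against day 9, for 16 lists in the sensitive effect in EC against bulk, and for 50 genes and 9 lists in the resistant effect, but no list held with an estimated correlation (smallest adjusted p = 0.7, 0.0949 and 0.596), and chance is not excluded for the 50 genes or the 16 and 9 lists. Among the 29099 probes without a gene name, which enter no comparison above, limma called 10906 in pooled EC (638 higher, 10268 lower), 15080 in resistant EC against vehicle (1869 and 13211), 15017 against sensitive mice (1902 and 13115), 289, 2769 and 3870 in the pooled, resistant and resistant against sensitive bulk comparisons, 1 at day 9, 9 at 600 mm3, 2 in their difference, and 4836 in EC against bulk (2859 and 1977).

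Other splits of the same samples show where chance is an unlikely account of gene counts, without adjustment over the split tests. It is unlikely for pooled EC (1 of 100 splits gave as many as 4416, highest other 2927) and EC against bulk (1 of 100, 9468, highest other 5586). In pooled EC the splits move the resistant arrays of slide 4 between groups, so they cannot tell sunitinib from slide or resistance. For pooled bulk at 1300 mm3 the share of splits was under 0.05 (3 of 100, 138). The highest other there was 4472, which points to a structure of the samples, so chance is not taken as excluded. Nor can chance be excluded for bulk resistant against vehicle (3 of 35 as many as 1313, highest other 3194), bulk resistant against sensitive (2 of 35, 2050, highest other 3089) or the resistant difference of fractions (2 of 35, 50, highest other 492), where again other splits called more. With 0 genes called, all 35 splits gave as many for sensitive EC (highest other 0), sensitive bulk (137) and the sensitive difference of fractions (0). For the average of day 9 and 600 mm3 the 18 splits are too few (real 0, highest other 585). For resistant against sensitive EC the highest other was 0 among the 8 splits that part 3 pairs, among the 12 that part 2 if resistant mouse 4 is mouse 6 (also too few), and among all 35.

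List counts by camera were matched by many other splits, so chance cannot be excluded for them. As many lists were called by 39 of 100 splits in pooled EC (13, highest other 22), 20 of 35 in sensitive EC (12, 21), 22 of 35 in resistant EC (10, 20), 4 of the 8 that part as many pairs in resistant against sensitive EC (13, 17), 98 of 100 in pooled bulk (2, 18), 35 of 35 in sensitive (4, 17), resistant (1, 15) and resistant against sensitive bulk (1, 14), 9 of 100 in EC against bulk (18, 22), 5 of 35 in the sensitive (16, 19) and 24 of 35 in the resistant difference of fractions (9, 18). For the average of both stages the 18 splits are too few (6 gave as many as 12, highest other 17).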

How the results depend on the processing

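Added after the data had been seen were normexp with the median of all genes brought to that of the main setting, resistant mouse 4 taken as mouse 6, and the tests on genes well above background on every array, without doubted arrays, on 1 slide, in resistant mice alone, and with the muscle covariate. The 15 gene counts stayed within 1.5 times their value in 80 of 112 alternatives set beforehand and 111 of 164 with an array left out; called lists kept direction and call in 852 of 1006 and 1399 of 1556, reversing in 6 of each, and named genes kept their call, or the lack of one, in 1624 of 1800 and 2472 of 2812, no gene that had passed reversing, while values of genes that had not passed changed sign in some. In what follows the cause was not tested unless stated. Quantile scaling gave 2871 genes in pooled EC, 284 in pooled and 2265 in resistant bulk, 1 at day 9 and 152 in the resistant difference of fractions, and medians of -0.03 for immediate early genes in resistant against sensitive EC and, in the resistant difference of fractions, -0.022 for glycolysis and -0.003 for antigen presentation genes. Normexp gave 1825 in pooled EC, 70 in pooled bulk, 1 at day 9 and 3 in the average of both stages. The deposited values gave 2579 in pooled EC, 270, 2314 and 3121 in pooled, resistant and resistant against sensitive bulk, 1 at day 9, 1 in the average and 183 in the resistant difference, with medians of -0.016 for immediate early genes in resistant against sensitive EC and -0.015 for antigen presentation in the resistant difference. No filter gave 84 in pooled bulk, 171 at 600 mm3 and 15 in the difference of stages, and the mean of probes 75 in pooled bulk. Mouse numbers as a block gave 20, 2, 418 and 785 in pooled, sensitive, resistant and resistant against sensitive bulk and 0 in the difference of stages; with resistant mouse 4 as mouse 6 the bulk counts were 0, 1, 131 and 217. The joint fit of 24 arrays gave 1465 in pooled EC and 523, 1, 2641 and 3695 in the same bulk order. The epithelial covariate gave an epithelial median of 0.014 in sensitive EC, by construction. Of list calls, 145 in all, 0 held with an estimated correlation and 38 by fry, which called 56 in all.

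Normexp with the median brought back gave 1371 in pooled, 4648 in resistant and 4106 in resistant against sensitive EC. Among genes well above background on every array limma called 1332 in pooled, 4469 in resistant and 4369 in resistant against sensitive EC, 52 in pooled bulk and 4 in the resistant difference, by a filter that removes genes that fell out of detection, and the adipocyte median was 0.163 in pooled EC. Without bulk resistant mouse 2 and vehicle mouse 3 the bulk counts were 2725 pooled, 7 sensitive, 5979 resistant and 6967 resistant against sensitive, and the endothelial median in sensitive bulk was 0.058; without both mice 1 and 229 genes passed in the sensitive and resistant differences of fractions, and the immediate early median was 0.143. The shared slide alone gave 8 in sensitive bulk; resistant mice alone gave 94 in EC against bulk, and 382 without mouse 2, with fewer arrays. The muscle covariate gave 0 genes at 600 mm3 and 0 in the difference of stages, with muscle medians of 0.042 at day 9, -0.139 at 600 mm3 and -0.112 averaged, and at 600 mm3 0.364 for tip cell and 0.298 for basement membrane genes, by construction for muscle. With 1 array left out, the other one of its arm at the smaller stages being assumed to vary like the rest, counts ranged from 3288 to 5135 in pooled, 0 to 0 in sensitive, 7179 to 9168 in resistant and 6603 to 9206 in resistant against sensitive EC, 26 to 2590, 0 to 7, 664 to 5500 and 1146 to 6385 in the same bulk order, 0 to 2 at day 9, 4 to 489 at 600 mm3, 0 to 202 averaged, 2 to 94 in their difference, 8532 to 11954 in EC against bulk, and 0 to 2 and 0 to 424 in the sensitive and resistant differences of fractions. Medians reversed within ranges of -0.064 (without vehicle mouse 2) to 0.293 for cell cycle and -1.055 to 0.131 (without vehicle mouse 5) for neutrophil genes in sensitive EC, -1.348 to 0.058 for endothelial genes in sensitive bulk and -0.99 to 0.143 for immediate early genes in the sensitive difference (both without vehicle mouse 3), and -1.656 to 0.02 for fibroblast (without sunitinib mouse 1) and -1.613 to 0.161 for muscle genes (without vehicle mouse 2) at day 9. Signal over background limits genes dim on the resistant arrays. Bounds are given only where no array of the group had the gene well above background, and other dim genes are given as plain differences.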

Other observations

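Every gene and list value in this part was picked after the data had been seen. Several genes known from eosinophils were lower in the EC fraction of resistant mice; no fixed list held them and no set test was made, and 4861 of 17945 genes were called lower there, with a median of -2.02. Beside Prg2, whose mean fell from 2.67 (SD 1.94, n = 4) in vehicle mice to -3.70 (SD 1.55) in resistant mice, with sensitive mice at 0.20 (SD 0.69), limma called lower the peroxidase Epx (at least 10.4-fold, adjusted p = 0.000215), Prg3 (at least 5.87-fold), the eosinophil ribonucleases Ear1 (-4.05), Ear2 (-4.11) and Ear6 (-4.95), the eotaxin receptor Ccr3 (-3.86), the interleukin receptor subunit Il5ra (at least 5.13-fold), the lipoxygenase Alox15 (-3.95) and Siglecf (-2.88). Against sensitive mice Epx was at least 2.36-fold (adjusted p = 0.00993) and Il5ra at least 2.71-fold lower and Ccr3 differed by -2.82, while Siglecf at -1.61 did not pass. Sensitive mice themselves stood between, at -2.15 for Epx and -1.04 for Ccr3 against vehicle, none of which passed. In bulk of the same resistant mice none of these passed: Epx stood at -1.14 (SE 0.86, adjusted p = 0.468), Prg2 at -0.46, Ccr3 at -1.05 and Siglecf at -0.27. That bulk group holds mouse 2, whose median signal was -1.27 beside -4.50 to -4.43 in the others. Without it limma called 5500 genes there instead of 1313. Values of the eosinophil genes without mouse 2 are not given, so whether their falls were limited to EC stays open. The falls in EC share the slide of the resistant arrays.

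Immediate early and inflammatory scores had higher group means at 1300 mm3 than in smaller tumours. Mean immediate early scores per group lay between 3.9 and 4.9 at 1300 mm3 and between 0.91 and 1.41 in the smaller tumours, and mean inflammatory cytokine scores between 2.26 and 3.74 and between -0.37 and 0.09. Single arrays overlapped: bulk vehicle mouse 3 at 1300 mm3 stood at 1.57 and -0.32, and day 9 sunitinib mouse 2 at 2.02 and 0.47. Mean skeletal muscle scores were 2.51 and 3.15 in treated and vehicle tumours at day 9 and 0.65 and -3.03 at 600 mm3. These groups lie on different slides from those at 1300 mm3, and no test was made between them.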
